A study of Drosophila melanogaster with 6 samples.

How the data were processed

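Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on Drosophila melanogaster at the white prepupal stage, the brief stage at the start of metamorphosis when the larva stops moving and its cuticle is still white. The libraries fall into 2 groups of 3: DNA precipitated with a mouse monoclonal antibody whose listed target is tango, and input DNA that was not precipitated. Tango is the fly counterpart of vertebrate ARNT, a bHLH-PAS transcription factor that binds DNA as the partner of other bHLH-PAS proteins. The titles of the series and of all its libraries begin with TCF, while the antibody entry names tango. The labels do not settle which of these names describes the experiment, so the regions are called ChIP peaks here and are not ascribed to a protein. The labels do not say whether replicate libraries came from separate collections of animals.

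The values come from a single peak list for the whole series. Per the submitters' processing notes, the tools named are CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA and MACS2, and the build is BDGP5. The deposited list names FlyBase release 5 in its header and MACS in its source column. Each row gives a sequence name, a start and an end (1-based) and a peak score that the authors' peak caller assigned. Which statistic the score is, its threshold, the read filters, the treatment of reads that match several places and the way replicates and inputs were combined are not given in the sources used here. The score was therefore used only to rank, describe and compare peaks within the list. A peak caller's score can depend on read depth as well as on enrichment, so a score is not taken as a measure of occupancy. No value of any single library was used (columns of other samples: 0), so n is 1 list throughout, replicate error could not be estimated, and every test below compares peaks with peaks and not ChIP with input libraries. Read depth per library is unknown here, and no read-based interval or detection limit is given.

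Release 5 holds the chromosome arms X, 2L, 2R, 3L, 3R and 4, separate pieces of mapped heterochromatin (names ending in Het), and scaffolds that could not be placed, strung together into the artificial sequences U and Uextra. A position on U or Uextra is thus not a place on a chromosome. Peaks were grouped into arms, mapped heterochromatin, U and Uextra. No genome sequence was used, and the gene table at hand is of release 6, whose coordinates were not mixed with those of release 5. For that reason the planned comparisons with transcription start sites, gene features, sequence motifs and gene lists, including the genes for tango and pangolin, could not be made. They are not analysed here. Densities are per Mb of the span from the first peak start to the last peak end on a sequence, with assembly gaps included.

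Shares are given with 95% Wilson binomial intervals, which cover counting error only and treat peaks as independent. Clustering was tested by the median distance between midpoints of neighbouring peaks against 1000 uniform placements of the peaks on the same spans (two-sided permutation test, Benjamini-Hochberg adjustment over 10 sets of peaks). The smallest p these placements can give is 0.002. Median scores and widths were compared with a two-sided permutation test of 100000 resamples, adjusted over 6 comparisons, whose smallest p is 1e-05. Neighbouring peaks are not independent, so these p-values are too small by an unknown amount. For the ends of the 5 long arms, peaks with gaps under 5 kb were first joined, and the regions in the outer 2 Mb were compared with an even spread by a two-sided exact binomial test adjusted over 10 windows. Peaks of 3 kb or more are called broad. The rule for named items, fixed before the data were examined, took the 20 highest-scoring peaks by position. The strongest peaks on the arms alone, the broad class, the end windows and the comparison of scores between sequence groups were added after the list was seen. Alternatives were the top 50% and 25% of peaks by score and the joining of peaks across gaps under 500 bp, 5 kb or 20 kb. The tests were tried on simulated data. Uniform peaks gave 0 clustering calls in 20 runs and peaks of which 20% were moved beside another gave 20 in 20. For the end windows uniform peaks gave calls in 0 of 20 runs, and an X window at 3 times the density was called in 20 of 20. The median test made 0 calls in 10 runs without a shift and 10 in 10 with a shift of 10 score units. The simulated window and shift exceed the end ratios (at most 1.51 in windows of 2 Mb) and the score difference between Uextra and arms (3.07) found below. These runs therefore say nothing of the power for such smaller effects. Peaks without an effect were drawn independently, unlike those of the list. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.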

Results

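The series asked where in the white prepupal genome DNA was enriched by precipitation with the antibody listed against tango. Input DNA was sequenced as well, but how it entered the peak calls is not given in the sources used here. The 3 ChIP and 3 input libraries were represented by 1 list of 9881 peaks, which covered 5821 kb. Peaks were 201 to 11621 bp wide, with a median of 419 bp and quartiles of 301 and 580 bp. The narrowest width, 201 bp, was shared by 167 peaks. Scores ran from 6.41 to 1060.24 with a median of 21.84 and quartiles of 14.1 and 46.84. With no values per library, the spread between replicates could not be set beside any of the differences that follow.

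The first comparison was between parts of the genome assembly. Most peaks did not lie on the chromosome arms. Uextra, the string of unplaced scaffolds, held 6713 peaks, or 67.9% of the list (interval 67.0 to 68.9%). The 6 arms held 2355 peaks (23.8%, interval 23.0 to 24.7%), U held 473 (4.79%, interval 4.38 to 5.23%) and the mapped heterochromatin held 340 (3.44%, interval 3.10 to 3.82%). Peaks were spaced at 233 per Mb on Uextra, 47.8 per Mb on U, 40.8 per Mb in the mapped heterochromatin and 19.7 per Mb on the arms. They covered 9.92% of the span of Uextra and 2.05% of that of the arms. By covered length the difference was smaller, because arm peaks were wider: Uextra held 49.1% of the covered bases and the arms 42.1%.

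The peaks of Uextra also scored higher. In the top 25% of the list by score, 1916 of 2486 peaks (77.1%, interval 75.4 to 78.7%) were on Uextra and 496 (20.0%, interval 18.4 to 21.6%) on the arms. The median score was 24.31 on Uextra and 21.24 on the arms (permutation test, adjusted p = 1.2e-05). The size of this difference, 3.07, depended on the set of peaks: it was 5.89 among peaks under 1 kb wide. In the top 50% by score it was 10.71, but that set is chosen by the score itself and is no check on the difference. U, with a median of 15.9, and the mapped heterochromatin, with 15.12, scored lower than the arms (permutation test, adjusted p = 1.2e-05 for each). Median widths were 392 bp on Uextra, 383 bp on U and 456.5 bp in mapped heterochromatin against 575 bp on the arms (permutation test, adjusted p at most 0.00015). Scaffold lengths on U and Uextra were not used, so peak widths there can reflect the assembly. Within the mapped heterochromatin, 2RHet held 140 peaks, 3LHet 86, 3RHet 85, 2LHet 25, and XHet and YHet 2 each. The YHet pair had scores of 139.96 and 144.58, and 1 of the XHet peaks, at positions 19 to 772, scored 847.16.

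**Figure D1:**
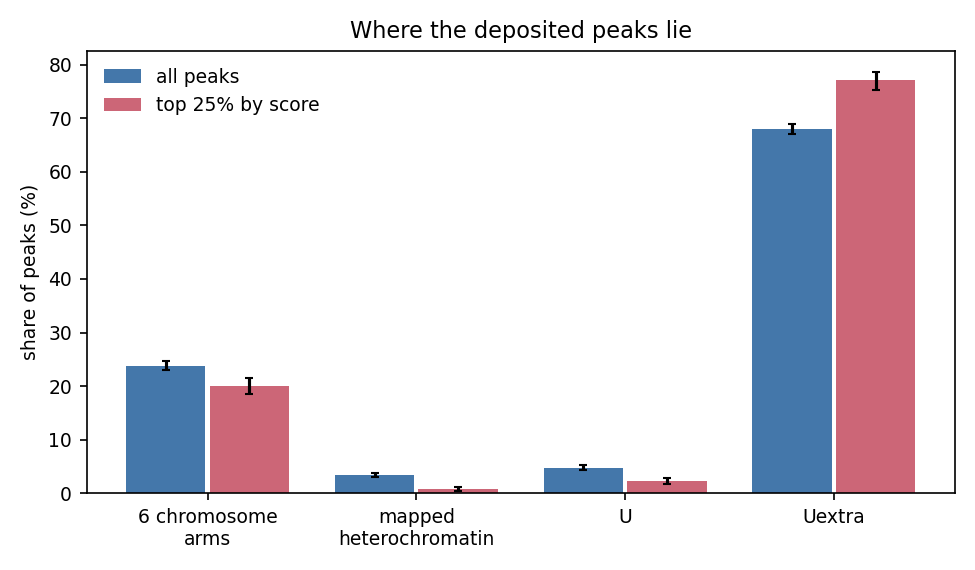
Share of peaks (%) on the arms, in mapped heterochromatin, on U and on Uextra, for all 9881 peaks and for the 2486 peaks of the top 25% by score; error bars are 95% Wilson intervals. Uextra holds 67.9% of all peaks and 77.1% of the top 25%.

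The strongest peaks were compared next. Of the 20 highest-scoring peaks, 13 were on Uextra, 5 on 2L, 1 on 3L and 1 on XHet. The highest score in the list, 1060.24, belonged to Uextra 25004608 to 25005454. On the arms the highest was 3L 18178706 to 18179496, a peak 791 bp wide with a score of 927.33. It was followed by 2L 479978 to 481610 with a score of 887.53 and a width of 1633 bp. Also among the 20 were 3 neighbouring peaks on 2L at 20176693 to 20183513, 20183582 to 20190095 and 20190256 to 20196890, with scores of 784, 779.97 and 797.14, and 2L 8204606 to 8205980 with 761.91. What genes lie at these positions was not analysed here.

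When the 20 highest-scoring arm peaks were taken alone, a set chosen after the scores were seen, 10 lay on 2L, 5 on 3R, 2 on 3L, 2 on X and 1 on 2R. Of these, 16 were compact, 673 to 1646 bp wide with a median of 963 bp. They included 3R 7603888 to 7605533 (score 754.91), 3R 11054707 to 11055736 (740.97), 2L 20864453 to 20865311 (730.07) and 3R 24983369 to 24984095 (698.6). The other 4 were 6372 to 6821 bp wide. They were the 2L trio and X 1521966 to 1528337, which scored 742.96. Among the compact peaks, 2L 20197412 to 20198116 lay 521 bp from the trio and X 1528849 to 1529563 lay 511 bp from the broad X peak. The 20 peaks are thus not 20 separate places, and the count on 2L includes neighbours.

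Among the arms, 3L held 533 peaks (22.6% of arm peaks), 2L 500 (21.2%), 3R 476 (20.21%), 2R 423 (18.0%), X 391 (16.6%) and 4 only 32 (1.36%). Per Mb of span these were 21.9 on 3L, 22.1 on 2L, 17.2 on 3R, 20.1 on 2R, 17.5 on X and 26.0 on 4. The release 5 arm lengths were not used, so no test of these counts was made. Median scores were 24 on X, 22.76 on 2L, 21.54 on 3R, 19.78 on 3L, 19.2 on 2R and 14.735 on 4. In the top 50% by score, X made up 19.0% of arm peaks, 3L 20.4% and 4 0.699%, each outside its interval in the whole list (15.2 to 18.2% for X, 21.0 to 24.4% for 3L, 0.964 to 1.91% for 4). The whole list contains this subset, so its intervals do not give the spread expected of the subset. The share of 4 rests on fewer than its 32 peaks.

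Arm peaks were clustered. The median distance between neighbouring midpoints was 12157.5 bp, against 34881.8 bp for peaks placed uniformly at random, a ratio of 0.35 (permutation test, adjusted p = 0.00222). The ratio was 0.28 on X, 0.29 on 2R, 0.32 on 3L, 0.34 on 2L and 0.45 on 3R (permutation test, adjusted p = 0.00222 for each). On chromosome 4, with 32 peaks, it was 0.82 and did not pass (permutation test, adjusted p = 0.326). The ratio was 0.13 in the mapped heterochromatin, 0.45 on U and 0.82 on Uextra (permutation test, adjusted p = 0.00222 for each). The placements could fall in assembly gaps, and on U and Uextra the order of scaffolds is artificial. The ratios there can therefore reflect the assembly rather than clustering on a chromosome. Of the gaps between neighbouring arm peaks 31.3% were under 500 bp. Once these were joined the ratio on the arms was 0.87, and in the top 50% by score it was 0.81, both still below random placement (permutation p = 0.002). Most of the departure from random placement thus lay in gaps under 500 bp. Whether such gaps split single regions was not tested.

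Joining arm peaks with gaps under 5 kb gave 1293 regions, of which 797 were single peaks and 71 held 5 or more, together 479 peaks. The region with the most peaks lay on 2R at 15620112 to 15653813, where 32 peaks with scores of 6.95 to 16.43 and a median width of 305.5 bp covered 14.7 kb of 33.7 kb. The next by number was X 3491695 to 3513626 with 12 peaks, whose highest score was 39.72. In bins of 1 Mb the fullest were 2R 15 to 16 Mb with 49 peaks, 2L 21 to 22 Mb with 48 and 3L 23 to 24 Mb with 42. After joining, these bins held 12, 20 and 16 regions.

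**Figure D2:**
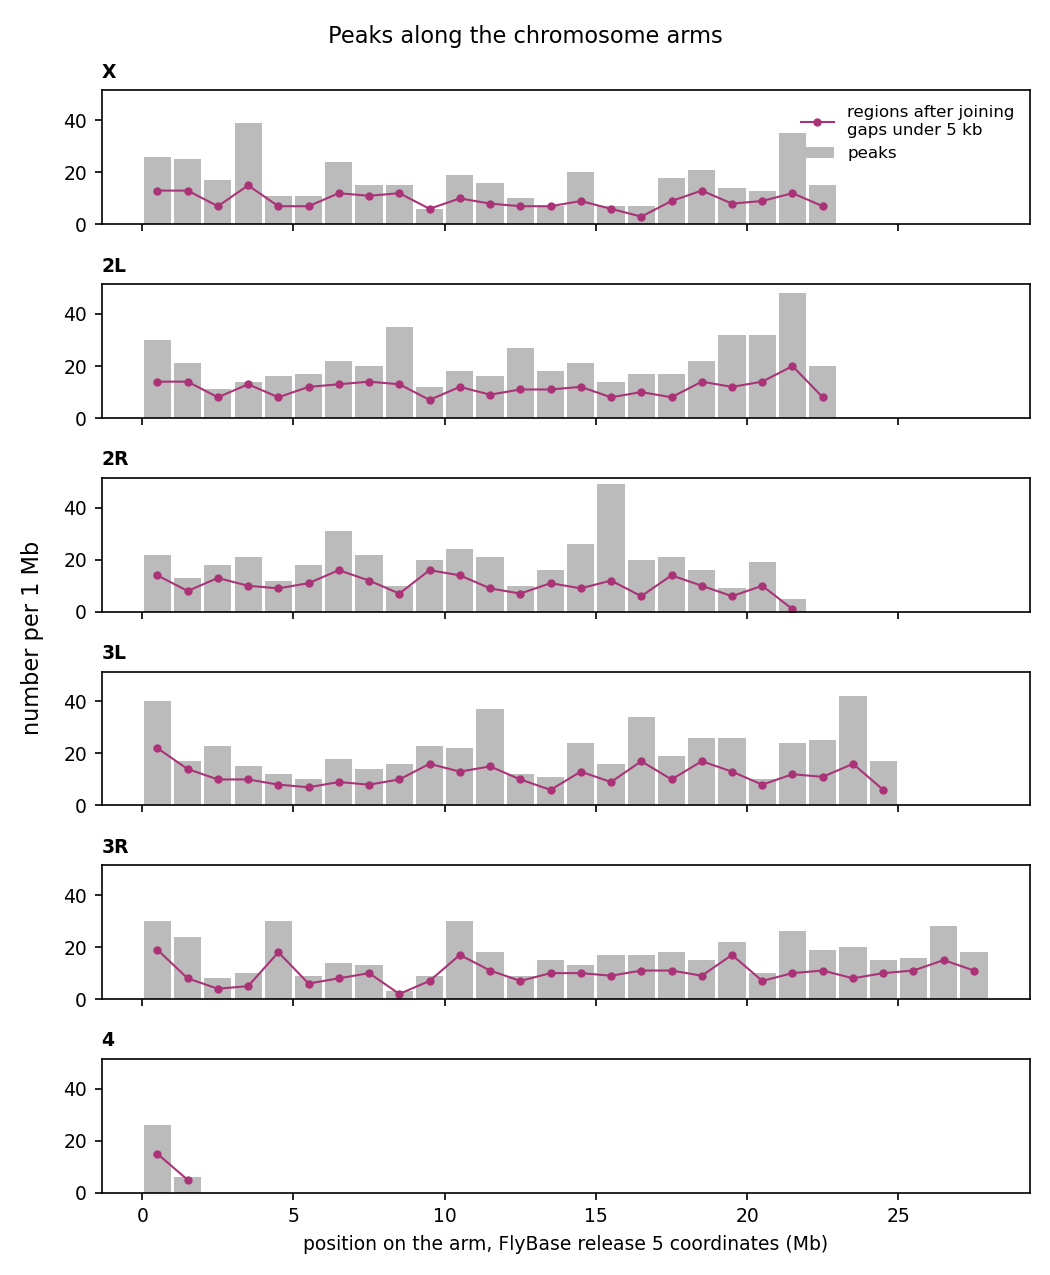
Number of peaks (grey bars) and of regions left after joining gaps under 5 kb (line) in each 1 Mb of the 6 arms, on FlyBase release 5 coordinates; the last bin of each arm is only partly filled. The bin of 2R at 15 to 16 Mb holds 49 peaks but 12 joined regions.

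The ends of the arms were compared with the rest, since the centromere side (the high end of X, 2L and 3L and the low end of 2R and 3R) borders heterochromatin. Of 10 windows of 2 Mb, 9 held more joined regions than an even spread would give, with ratios from 0.79 at the telomere end of 2R to 1.51 at the telomere end of 3L. By the exact binomial test 0 of the 10 passed after adjustment (lowest adjusted p = 0.134), and 1, the telomere end of 3L, had an unadjusted p under 0.05. With windows of 1 Mb, 3 passed the same exact test: the centromere end of X (ratio 1.91, adjusted p = 0.0359), the telomere end of 3L (1.85, adjusted p = 0.034) and the centromere end of 3R (1.97, adjusted p = 0.034). In the top 50% by score with windows of 2 Mb, 0 passed (exact test, lowest adjusted p = 0.363). The ratio was 0.99 at the centromere end of X, 0.74 at that of 3R and 0.57 at that of 2R, against 1.38, 1.33 and 1.03 for all peaks. It rose at the telomere ends of X (1.38 to 1.55) and 3R (1.38 to 1.48) and was lower than for all peaks at every other end. With gaps under 500 bp joined 0 passed, the nearest being the centromere ends of X and 3L (exact test, adjusted p = 0.0519 for each), and with gaps under 20 kb joined 0 passed (exact test, lowest adjusted p = 0.634).

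The width of a peak and its score were related differently on the arms and on Uextra. Across peaks, which are not independent replicates, Spearman's rho between width and score was 0.52 on the arms and 0.68 on Uextra. On Uextra the median score went from 15.9 for peaks under 400 bp to 35.95 at 400 to 600 bp, 73.17 at 600 to 1000 bp and 315.6 at 1000 to 2000 bp. On the arms it was 12.4, 23.215, 24 and 23.06 in the same classes, and 27.88 at 2000 to 3000 bp. The widest Uextra classes went the other way but held few peaks, with medians of 273.57 at 2000 to 3000 bp (5 peaks) and 43.115 at 3000 to 5000 bp (2 peaks), while on the arms the median was 28.55 at 3000 to 5000 bp and 45.22 above that. Broad peaks of 3 kb or more numbered 195 on the arms (8.28%, interval 7.23 to 9.46%) and 2 of 6713 on Uextra (0.0298%, interval 0.00817 to 0.109%), a limit chosen after the widths were seen. How far the length of its scaffolds limits peak width on Uextra is unknown here. The contrast in width, and in width against score, can therefore reflect the assembly. The broad peaks held 38.01% of the covered bases of the arms. Their median score was 34.13, against 19.78 for the other arm peaks. Of the broad peaks 5 of 195 (2.56%, interval 1.1 to 5.86%) reached the top 5% of the whole list by score, and of the others 86 of 2160 (3.98%, interval 3.24 to 4.89%), so their intervals overlapped. By arm, 54 broad peaks were on 2L, 44 on X, 38 on 3L, 30 on 2R and 29 on 3R.

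**Figure D3:**
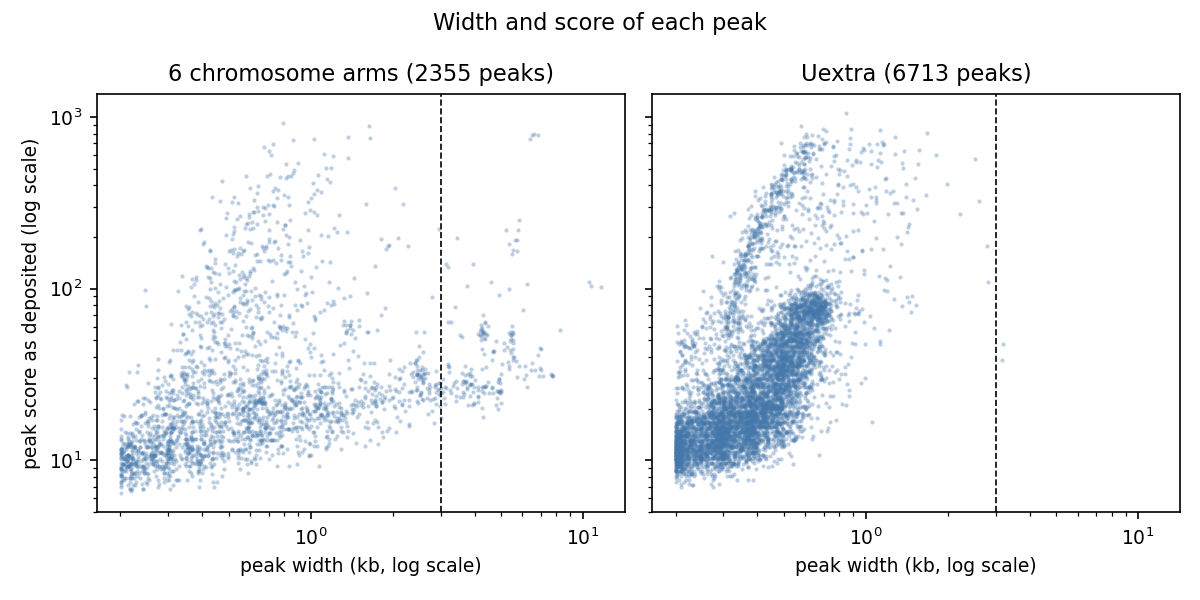
Width (kb, log scale) against score as deposited (log scale) for the 2355 arm peaks and the 6713 Uextra peaks, 1 point per peak; the dashed line marks 3 kb. The arms have 195 peaks to the right of the line, with a median score of 34.13, and Uextra has 2.

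The largest broad peaks lay together on 2L between 21428108 and 21543676. There 16 peaks covered 68.9 kb of 115.6 kb, with a median score of 90.47 and a range of 20.95 to 109.01. They included the 3 widest peaks of the list, at 21430189 to 21440908, 21455286 to 21465795 and 21500597 to 21512217, which were 10720, 10510 and 11621 bp wide and scored 102.97, 109.01 and 102.42. This region was picked out after the widths were seen.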

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

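Of the alternatives, those on the top 50% and 25% by score and the joined gaps for the peak number, arm shares and clustering were fixed before the data were examined, and those on Uextra, the end windows and broad peaks were added afterwards. The list fell from 9881 peaks to 4985 in the top 50% and 2486 in the top 25% by score, by construction, and joining gaps under 500 bp left 7628. In the top 50% the shares of arm peaks became 19.0% on X, 20.4% on 3L and 0.699% on 4. The cause was not tested. The other arm shares stayed within their intervals. The share on Uextra was 73.0% in the top 50%, 77.1% in the top 25%, 71.1% with gaps under 500 bp joined, 47.7% with gaps under 5 kb joined and 49.1% of covered bases. Fewer gaps are under 500 bp on Uextra than on the arms (19.2% against 31.3%) but more are under 5 kb (77.3% against 45.2%), and Uextra peaks are narrower. The clustering ratio on the arms, 0.35 for all arm peaks, stayed below 1 and past the threshold in all 3 alternatives, though its size changed. It was 0.39 without the outer 2 Mb, an alternative added afterwards, and 0.81 and 0.87 in the others. The score difference between Uextra and arms went from 3.07 to 5.89 for peaks under 1 kb. It was 10.71 in the top 50%, a set chosen by the score itself that checks nothing here. In the end windows, 3 ratios passed only with windows of 1 Mb (1.91 at the centromere end of X, 1.85 at the telomere end of 3L and 1.97 at the centromere end of 3R). In the top 50% the ratio turned below 1 at the centromere ends of X (1.38 to 0.99), 3R (1.33 to 0.74) and 2R (1.03 to 0.57), with windows of 2 Mb and none of them past the threshold before or after. The 2R ratio was also below 1 with gaps under 500 bp (0.96) or 20 kb joined (0.92), and with those joins none of the 10 windows passed, the nearest at adjusted p = 0.0519 (exact test, centromere ends of X and 3L, 500 bp). The cause was not tested. Broad arm peaks numbered 304 at 2 kb or more and 67 at 5 kb or more, by construction. Alternatives fixed beforehand on start sites, features, motifs, gene lists and strength by motif or start site were not run, for want of the release 5 genome and annotation. No paired analysis was possible because the list carries no values for single libraries, and for the same reason no replicate could be left out. Depth per library is unknown here.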

Other observations

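These patterns were noticed in the list, and every value here was computed after the list had been seen. For the share in the top 25% by score, the share after joining gaps under 5 kb, the pair count and the neighbour count, the expected outcome was written down before the value was computed, but after scores and widths by group had been looked at. On Uextra, fewer peaks 500 to 600 bp wide scored between 90 and 180 than at 180 or more. Only this width class was counted, and its limits were chosen after the plot was seen. Of the 1012 Uextra peaks 500 to 600 bp wide, 879 (86.9%) scored below 90, 26 (2.57%) between 90 and 180, and 107 (10.6%) at 180 or more. Of the 224 arm peaks of that width, 173 (77.2%), 35 (15.6%) and 16 (7.14%) did. The strong Uextra peaks were not spread evenly. Of the 405 peaks beyond 28 Mb, 245 (60.5%, interval 55.7 to 65.1%) scored 100 or more, against 442 of the other 6308 (7.01%, interval 6.40 to 7.66%). Both limits were chosen after this was seen, so no test is given. The last Mb of Uextra also held the most peaks, 405, against 36 in the first Mb. After joining gaps under 5 kb these bins held 38 and 25 regions, and the most, 69, lay at 7 to 8 Mb. Such a join merges more neighbours where peaks are denser, even if placed at random, so these region counts do not qualify the peak counts. The scaffolds behind these positions were not analysed here.

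Part of the 2L trio resembled a pair of peaks on X, a likeness noticed in the list and not counted against other broad peaks. On 2L the peak at 20190256 to 20196890 (6635 bp, score 797.14) was followed after 521 bp by one of 705 bp at 20197412 to 20198116 (score 630.12). On X the peak at 1521966 to 1528337 (6372 bp, score 742.96) was followed after 511 bp by one of 715 bp at 1528849 to 1529563 (score 596.15). The 2 wide peaks differ in width by more than the 2% used below for pairs alike in width. A short peak beside a broad one also occurred elsewhere, as at 3R 1272409 to 1278185 (5777 bp), next to a peak of 392 bp. In the cluster of broad peaks on 2L between 21428108 and 21543676, 3 gaps between neighbouring peaks were exactly 9999 bp long. Of the 240 gaps of 5 to 20 kb on the arms, 4 had that length, and no other length occurred more than 2 times.

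The share of peaks on Uextra was set against 2 technical explanations. Weak calls near the threshold would make the share fall among stronger peaks, but it was 77.1% in the top 25% by score, against 67.9% in the whole list. The higher scores of Uextra peaks had been seen before this expectation was written, so the value restates them and is no independent test. Single regions split at short gaps would make the share fall once gaps under 500 bp are joined, but it was 71.1% then. This expectation was written afterwards. Fewer gaps were under 500 bp on Uextra (19.2%) than on the arms (31.3%), so the rise restates those counts and is no separate test. Joining gaps under 5 kb brought the share on Uextra to 47.7%. That decides nothing, since peaks placed uniformly at random at the same density gave 41.1% (range 40.4 to 41.99% over 100 placements). Reads that match many repeated copies, and a difference in copy number between the animals and the assembly that the input did not remove, stay open, because neither reads nor sequence were used. The design has no group that would test a biological explanation, and none was tested.

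A candidate explanation for the broad arm peaks is that many are copies of repeated elements of fixed length that share reads, which would give peaks alike in both width and score. Of 992 pairs of the 195 broad peaks with widths within 2% of each other, 216 also had scores within 10%. This was 1.14 times the 189 expected from shuffling scores within blocks of up to 20 peaks ranked by width (10000 shuffles, one-sided permutation p = 0.0085, highest shuffle 231). Widths in a block can differ by more than 2%, so a trend of score with width could add to this excess. Neighbours count as pairs too, as 2L 20183582 to 20190095 with 20190256 to 20196890. The idea came from like scores seen in the broad peaks themselves, so this count of pairs cannot establish it. As an example chosen after the plot was seen, the 40 arm peaks 4.1 to 4.5 kb wide had scores of 17.79 to 28.55 in 15 cases and of 44.42 to 69.83 in 22, with 3 between. A second explanation is that the caller joined narrow neighbouring sites. Of the broad peaks 74.4% (145 of 195, interval 67.8 to 80.0%) had another peak within 1 kb, against 51.9% of the other arm peaks (1120 of 2160, interval 49.7 to 54.0%; one-sided permutation p = 1e-04, the smallest 10000 shuffles can give). Such a neighbour is a site that was not joined, and a repeated element with a split-off end would leave one too, so this share favours neither explanation. The excess of pairs is small, and both explanations remain hypotheses. Matching the intervals to annotated repeats of the same build would separate them.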
